A study of Mus musculus with 12 samples.

How the data were processed

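Chromatin accessibility was measured by ATAC-seq, in which the transposase Tn5 inserts sequencing adapters into open chromatin, in 12 libraries of mouse alveolar macrophages (AM), 3 in each of 4 groups. BAL AM came from bronchoalveolar lavage, exAM were expanded ex vivo for 2 months, texAM were recovered 4 months after exAM had been transplanted into the airways of recipient mice, and Host AM were the recipients' own cells. Each reaction used 5000 cells. The sample labels give a pool of 3 mice for each library, whereas the series design gives pools of 2 to 3 mice for the transplanted and host cells. The design also calls the triplicates technical transposase reactions. The p-values therefore measure a spread between libraries that may be technical, and n = 3 stands for 3 libraries in every group.

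Reads were trimmed with cutadapt 2.6 and aligned with Bowtie2 2.3.5.1 to GRCm38 (mm10), per the submitters' processing notes, which also name FastQC 0.11.6, Genrich 0.6.1 and bedtools 2.26.0. The authors deposited no count, normalised or signal column. Each library's deposited intervals have the layout that Genrich writes in its ATAC mode, with 150 bp around each end of a fragment and up to 300 bp where both ends of a short fragment were joined. The authors also deposited 1 set of 48100 consensus regions, as positions alone, over all 4 groups. How that set was filtered, and whether PCR duplicates had been removed before deposit, is not given in the sources used here. Fragments sharing both ends made up at most 0.283% of a library. No interval lay on the mitochondrial chromosome. Deposited positions count from 0 and are printed here counted from 1.

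Counts were made from the deposited intervals by assigning an interval to the region that held its midpoint. The 48090 regions on autosomes and X, of median width 1340 bp, were analysed, and the 10 on Y were left out. A region was tested if at least 10 counts were present in at least 3 libraries, which left 46271 regions. Counts were scaled by median-of-ratios size factors over the regions, so every change is relative to the median region. Normalised counts are counts divided by these factors. Regions were assigned to the nearest protein-coding gene within 50 kb of its span in the RefSeq annotation of GRCm38.p6, because that table gives no strand and therefore no transcription start. This departs from the planned nearest start site. It placed 44217 regions at 13839 genes, and the counts over all regions of a gene were summed into a locus value. In all, 13603 loci were tested. Exons, introns and untranslated parts are not told apart by that table, so a region is described as inside a gene, within 1 kb of a gene end, or between genes.

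Groups were compared with limma-voom (limma 3.58.1 and R 4.3.3, with tables read by the data.table package, version 1.17.8) in 1 group-means fit over all 12 libraries, two-sided, with Benjamini-Hochberg adjustment at a false discovery rate of 0.05. Fold changes are on the log2 scale with the standard error (SE) of the fit, and group means are normalised counts ± SD. The comparisons, tests and gene lists were fixed before the data were examined. So was the rule for named genes. For each comparison of regions it took the 10 largest changes in each direction among regions past the threshold that changed at least 2-fold, had a mean normalised count of at least 17.55, the median, and showed no overlap between the libraries of both groups, with 1 region per gene. Chance alone gives no overlap in 10% of regions with 3 libraries against 3. For each list the rule took up to 4 loci past the threshold, or 2 where none passed, and Pparg, Car4, Siglecf, Marco, Maf and Ptprc were always given. The text names part of this selection, and some of it is not reported here.

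The 18 lists covered alveolar macrophage identity, lipid and cholesterol handling, cytoskeleton and adhesion, inflammatory NF-kB, interferon response, antigen presentation, cell cycle and self-renewal, monocyte and other tissue macrophage, TGF-beta response, and oxidative stress and hypoxia. Markers of T cells, B cells, neutrophils, eosinophils, dendritic cells, epithelium, endothelium and fibroblasts made up the others. Of 379 symbols, 377 matched the annotation (Mx1 and Mx2 did not). Lists were tested with camera at its preset correlation of 0.01, adjusted over the 18 lists of a comparison, and again with an estimated correlation. A culture score per library was the mean log2(normalised count + 1) over regions called higher in exAM than in BAL AM, in a fit of those 6 libraries alone, minus the mean over regions called lower. It was compared between texAM and Host AM by an exact two-sided permutation test, which with 3 libraries against 3 cannot give a p below 0.1. Counting, tests of scores and plots used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.

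The fits were tested on simulated counts with known changes, placed only in regions or loci whose mean count was at or above the median. Recovery at lower counts was not tested. All 4 groups were drawn with the same spread for regions or loci of similar mean count. Differences in spread between groups were therefore not simulated. Among 46271 simulated regions, 86.4% of those changed 4-fold and 47.8% of those changed 2-fold were recovered for exAM against BAL AM, and 62.1% and 20.9% for texAM against exAM. For texAM against Host AM the shares were 66.7% and 29.9%, for texAM against BAL AM 69.7% and 22.4%, and for Host AM against BAL AM 92.4% and 47.8%. Changes of 1.5-fold were recovered in 1.49% of regions for texAM against Host AM, so small differences there were not detectable at this depth. Among 13603 simulated loci, 91.0% (exAM against BAL AM), 80.6% (texAM against exAM), 80.6% (texAM against Host AM) and 98.5% (Host AM against BAL AM) of 2-fold changes were recovered. False calls numbered at most 14 in any of these fits. For regions of exAM against BAL AM, 10 false calls stood beside 6, 32 and 57 recovered changes of 1.5-fold, 2-fold and 4-fold. Intervals per library ranged from 2174604 to 10871325. The shallowest library, texAM 2, had 18.4% of its intervals in regions with a Wilson 95% interval of 18.35 to 18.45%. This covers counting error only, with intervals treated as independent.

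Alternatives covered scaling (total counts in regions, total intervals, 10-kb bins, quantile, cyclic loess), the count filter, the counting rule, thinning to the smallest library, other limma settings, the 6 libraries of a comparison alone, the replicate block, the fold and discovery thresholds, each library left out in turn, the distance used to assign genes, short fragments and background. Motif analysis, which needs a genome sequence, was not run.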

Results

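ATAC-seq profiles were collected from 4 groups of mouse alveolar macrophages, the resident phagocytes of the airspaces. BAL AM were unsorted cells from the lungs of 8-week-old C57BL/6 mice, obtained by lavage. exAM were the same kind of cell after 2 months of expansion in culture, also unsorted. texAM were cultured cells that had been transplanted into the airways of mice carrying the CD45.1 form of the pan-leukocyte protein Ptprc, and were sorted from the lungs 4 months later as CD45.2+ cells. Host AM were the CD45.1+ alveolar macrophages of the same recipients, sorted with the same gate for live cells positive for SiglecF and CD11c. Each group had 3 libraries. The design asks what culture does to alveolar macrophage chromatin, what return to the lung does to cultured cells, and how transplanted cells compare with resident ones.

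The libraries held 5411078 to 7011438 intervals in BAL AM, 4617242 to 6351110 in exAM, 2174604 (texAM 2) to 5889271 in texAM and 4626773 to 10871325 (Host AM 2) in Host AM. The share of intervals inside the consensus regions was 40.0% ± 4.99 in BAL AM, 26.0% ± 0.688 in exAM, 17.8% ± 0.920 in texAM and 21.7% ± 1.47 in Host AM (SD, n = 3). Fragments under 150 bp made up 18.2% ± 2.67 in BAL AM and 15.6% ± 4.05 in exAM, against 46.3% ± 14.2 in texAM and 40.8% ± 15.6 in Host AM. The 6 sorted libraries thus held fewer intervals in regions (19.8% against 33.0%) and more short fragments (43.6% against 16.9%) than the 6 unsorted ones, each at an exact two-sided permutation p of 0.00216. That test treats the 12 libraries as independent, although they are triplicates of 4 groups, so its p overstates the evidence. Sorting, tissue source and recipient history went together in these groups, so the comparisons of a sorted with an unsorted group carry this difference as well. The share in regions also differed between the unsorted groups (40.0% in BAL AM, 26.0% in exAM), so exAM against BAL AM carries that difference too. texAM 2 (62.2%) and Host AM 2 (58.6%) had the most short fragments. No pair of replicate libraries held the same counts, with a chi-square per region of 2.04 to 2.98. Longer fragments gave 2 intervals, which are not independent draws, so part of this can come from resampling alone. The chi-square does not tell whether replicates were technical.

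**Figure D1:**
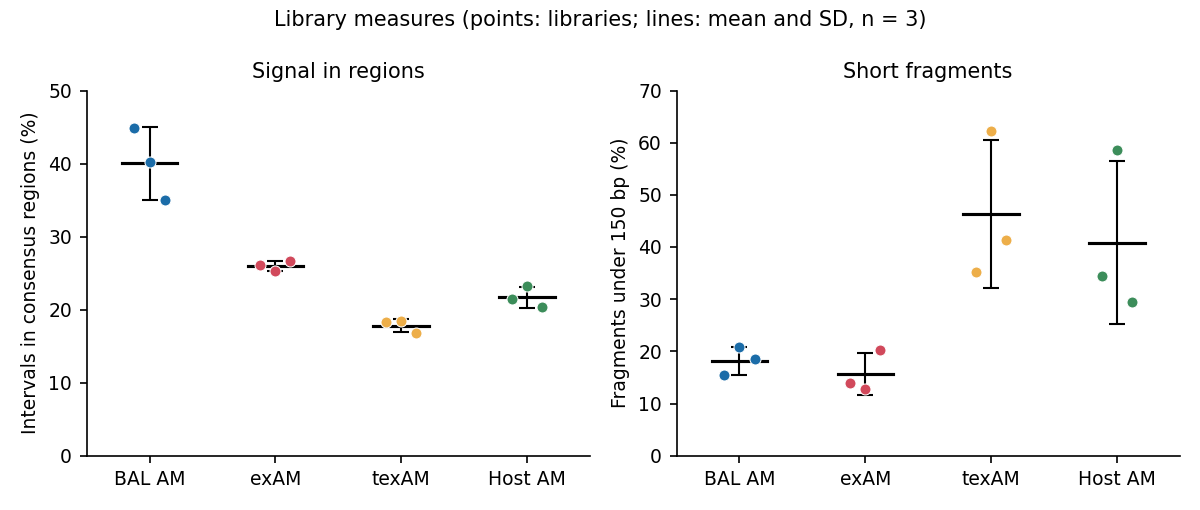
Each point is 1 library, grouped by cell population along the horizontal axis, and the panels show the percent of intervals inside consensus regions and the percent of fragments under 150 bp, with lines for the group mean and SD (n = 3). BAL AM libraries lie highest in the percent inside regions (34.96 to 44.92%), and texAM and Host AM libraries lie highest in short fragments.

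Accessibility profiles separated the cultured cells from the 3 populations taken from lungs. Across regions, which are not independent of each other, the mean Spearman correlation between BAL AM and Host AM libraries was 0.847, and between BAL AM and texAM libraries 0.791. It was 0.781 between texAM and Host AM, 0.701 between BAL AM and exAM, 0.690 between texAM and exAM, and 0.679 between exAM and Host AM. Within groups it was 0.899 in BAL AM, 0.836 in exAM, 0.835 in Host AM and 0.765 in texAM. In a principal component analysis texAM 2, the shallowest library, lay apart from the other texAM libraries.

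Culture was examined by comparing exAM with BAL AM, both unsorted. The locus of Marco, a scavenger receptor of alveolar macrophages, rose by 1.21 ± 0.10 log2 (SE, adjusted p = 3.1e-12), from 416 ± 25.6 to 951 ± 144 normalised counts. Cd36, a fatty acid and lipoprotein receptor, rose by 1.02 ± 0.09 (2.21e-11), and Smurf1, a ubiquitin ligase that acts on TGF-beta signalling, rose by 1.75 ± 0.14 (1.89e-12). The locus of Il10, an anti-inflammatory cytokine, rose from 8.37 ± 2.31 to 48.0 ± 17.4. Lower in exAM were the loci of Chil3, a chitinase-like protein abundant in alveolar macrophages (-1.38 ± 0.16, adjusted p = 2.45e-08), Fn1, which encodes fibronectin (-2.11 ± 0.29, 5.48e-07), Tgfbi (-1.45 ± 0.13, 5.74e-11) and Pmepa1 (-1.78 ± 0.18, 1.66e-09), the last a TGF-beta-induced inhibitor of the same pathway.

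Among single regions, 5692 were higher and 3386 lower in exAM, together 9078 of 46271 tested, with a median absolute change of 1.42 log2 among those called. The largest gains included a region between genes near Stac (chr9:111708940-111710159, GRCm38), which went from 1.68 ± 1.08 to 68.5 ± 19.8 normalised counts (5.30 ± 0.72 log2, adjusted p = 1.83e-07). A region between genes near S100a7l2 (chr3:91044221-91046633) went from 2.78 ± 0.961 to 87.5 ± 19.6 (4.80 ± 0.53, 9.57e-10). A region inside Dpp6 (chr5:27303220-27305132) changed by 4.42 ± 0.42 (1.21e-11). Among the largest losses, a region inside Sptbn1 (chr11:30197384-30199453), which encodes a spectrin, went from 68.0 ± 5.38 to 3.47 ± 4.62 (-4.96 ± 0.86, 2.25e-05). Regions within 1 kb of a gene end made up 16.4% of the regions that were higher and 24.0% of those that were lower, against 28.03% of all regions tested. All 20 regions named by the rule kept their call when any 1 library was left out. At the level of loci, 3023 of 13603 passed, 1073 of them lower in exAM and the rest higher.

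These directions are relative to the median region, and scaling set how many regions counted as higher. Scaled by total intervals the split was 2114 higher and 18358 lower, with the median region at -0.67 log2, and scaled by 10-kb bins it was 1261 higher and 25774 lower, with the median region at -0.99. With the bins, the rises at Marco (0.19), Cd36 (0.01), Ctsk (0.35), Fabp4 (0.27), Scd1 (0.01), Id3 (0.08) and Itgb8 (0.12) no longer passed, whereas those at Smurf1, Il10, Foxm1, Spic and Col3a1 did. Counted in the 500 bp around region centres, Chil3 did not pass (-0.10), and with regions within 1 kb of a gene end alone Pmepa1 did not (-0.61).

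Antigen presentation was the list that passed as a set in exAM by camera at its preset correlation (adjusted p = 0.0018), but not with an estimated correlation (adjusted p = 0.312). Of its 21 measured members 9 fell, none rose and 12 did not pass, with the same counts (0 rose, 9 fell) when adjusted over the list alone and at an unadjusted p under 0.05. Cd74, the invariant chain of MHC class II, fell by 1.22 on the log2 scale (SE 0.18, adjusted p = 1.65e-06), from 367 ± 50.4 to 161 ± 59.6 normalised counts. Ciita, the class II transactivator, went from 133 ± 5.94 to 71.2 ± 34.3 (-1.04 ± 0.20, 0.000167), which did not pass with regions within 1 kb of a gene end alone (-0.12). H2-Aa also passed, but not without exAM 2 (adjusted p = 0.0548) or exAM 3 (0.0786), and H2-Eb1 not without exAM 2 (0.0617).

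None of the other macrophage lists passed as a set in exAM, and most had members moving in both directions. Of 32 alveolar macrophage identity loci 7 rose and 9 fell (camera adjusted p = 0.614), with Ctsk, a cathepsin, at 1.37 (4.46e-07) and Fabp4, a lipid-binding protein, at 1.26 (8.15e-07) among those that rose. Lipid and cholesterol handling had 4 loci that rose and 4 that fell of 32 (0.811), with a median of 0.01 and a mean of 0.04 although the test, which sets the list against all loci (median 0.06), pointed down. Cytoskeleton and adhesion had 9 and 9 of 33 (0.75). Inflammatory NF-kB had 6 that rose, Il10 among them, and 9 that fell, Cxcl3 among them (-1.47, 0.000111), of 29 (0.75), with a median of 0.00 and a mean of 0.08 against a test pointing down. For that list 7 rose and 9 fell when adjusted over the list alone. TGF-beta response had 4 that rose and 7 that fell of 20 (0.264), or 6 and 9 adjusted over the list alone. Cell cycle and self-renewal had 7 and 6 of 29 (0.823), with Foxm1, a transcription factor of dividing cells, at 3.04 (0.000356), and its median of 0.08 and mean of 0.16 lay above 0 while the test pointed down. In the monocyte and other tissue macrophage list 8 rose and 1 fell of 24 (0.264), including Spic at 2.92 (0.000257). The BAL AM libraries held 1.21 to 4.16 normalised counts at Foxm1 and 1.25 to 4.16 at Spic, so these folds rest on few counts. Oxidative stress and hypoxia had 7 loci that rose and none that fell of 24 (0.264; 10 and 1 at an unadjusted p under 0.05), although its members Pgk1 (0.92) and Ldha (0.74), both enzymes of glycolysis, lay at -0.05 and -0.24 when scaled by 10-kb bins. In the interferon response list 1 of 23 loci, Ifih1 (-0.57, adjusted p = 0.0416), fell, a call lost without BAL AM 2 (0.177), exAM 1 (0.0753), exAM 2 (0.0872) or exAM 3 (0.139), and the list gave 0.532. No interferon locus passed when adjusted over the list alone (2 higher and 3 lower at an unadjusted p under 0.05).

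Markers of other cell types were measured beside these lists. Of 55 such loci that could be measured, 9 rose and 3 fell in exAM, while 14.34% of all loci rose and 7.89% fell. The markers thus moved about as often as other loci. By list, 2 of 4 eosinophil, 2 of 12 dendritic cell, 1 of 10 epithelial, 3 of 9 endothelial and 1 of 4 fibroblast loci rose, and 1 of 7 T cell, 1 dendritic cell and 1 epithelial locus fell. None of the 4 B cell and 7 neutrophil loci passed in limma-voom (1 of each at an unadjusted p under 0.05). Col3a1, a fibrillar collagen of fibroblasts, went from 2.61 to 58.5 normalised counts (4.44, adjusted p = 7.46e-07), and Sox17, an endothelial transcription factor, rose by 2.58. At Sox17 the BAL AM libraries held 2.08 to 4.24 normalised counts, so its fold also rests on few counts. The camera adjusted p was 0.561 or more for each of these lists. Scaled by total intervals, the rises at the markers Rnase2a (-0.025), Ear6 (-0.239), Tcf4 (-0.155) and Vwf (-0.095) turned, whereas those at Col3a1 and Sox17 kept their direction.

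Of the loci given in every comparison, Pparg, the transcription factor of alveolar macrophage identity, went from 523 ± 42.2 to 777 ± 129 normalised counts (0.55 ± 0.10 log2, adjusted p = 2.35e-05), but lay at -0.11 when scaled by total intervals and at -0.43 when scaled by 10-kb bins. Car4, a carbonic anhydrase, was at 0.67 (0.0109), which turned to -0.30 with the bins and did not pass without BAL AM 2 (0.0982) or exAM 2 (0.142). Siglecf, whose product is a sort marker, went from 153 ± 16.3 to 101 ± 7.92 (-0.58, 0.00518). Maf was at -0.61 (0.0392), a call that did not hold without BAL AM 1 (0.0516), BAL AM 2 (0.148), exAM 1 (0.0827), exAM 2 (0.134) or exAM 3 (0.0776). Ptprc (-0.24, 0.124) did not pass.

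**Figure D2:**
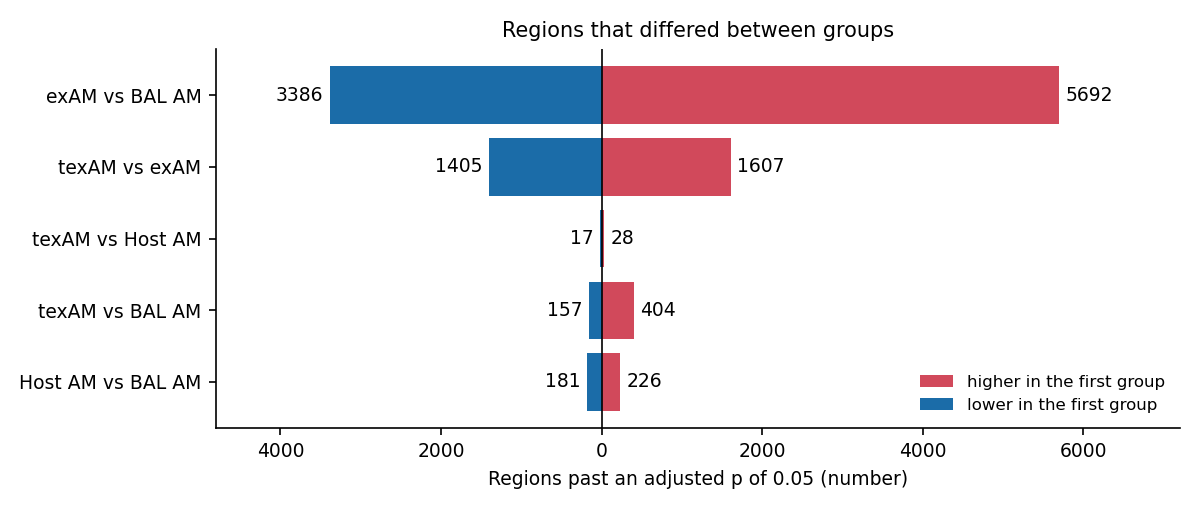
Bars give the number of regions, out of 46271 tested by limma-voom under the scaling by consensus regions, that were higher (right of 0) or lower (left of 0) in the first group of each comparison at an adjusted p of 0.05. The comparison of exAM with BAL AM has the most (5692 higher and 3386 lower) and that of texAM with Host AM the fewest (28 and 17). The split between higher and lower moves with other scalings. The order moves too, as limma-trend called 129 regions for texAM against Host AM and 79 for Host AM against BAL AM. The median SE was 0.490 and 0.361 in these comparisons, so the counts do not rank the sizes of the differences.

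Return to the lung was examined by comparing texAM with exAM, a sorted with an unsorted group. Several loci that had been higher in exAM than in BAL AM were lower in texAM than in exAM, in comparisons that share the exAM libraries. Ctsk fell by 2.01 (SE 0.31, adjusted p = 1.58e-05), Smurf1 by 1.41 (SE 0.17, 2.13e-07), to 144 ± 15.1 normalised counts, and Cd36 by 0.86 (SE 0.11, 8.14e-07), to 434 ± 23.4. Marco, at 555 ± 61.5 in texAM, fell by 0.75 (2.64e-05) and Pparg by 0.60 (0.000788). The locus of Il1a, an inflammatory cytokine, fell by 1.33 (SE 0.17, 7.59e-07). Higher in texAM were Cd74 (1.44 ± 0.20, 2.63e-06), at 462 ± 146 normalised counts, H2-Aa, an MHC class II chain (1.92 ± 0.40, 0.00115), which went from 14.0 ± 3.79 to 60.1 ± 20.3, and Ly6c2, a surface protein of monocytes (1.60 ± 0.19, 1.82e-07), which did not pass with regions within 20 kb alone (0.19).

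Among single regions, 1607 were higher and 1405 lower in texAM than in exAM (3012 of 46271), and among loci 684 rose and 894 fell. A region inside Foxn3 (chr12:99212599-99214742), which encodes a forkhead factor, went from 6.26 ± 3.37 in exAM to 113 ± 3.90 in texAM (4.12 ± 0.50 log2, adjusted p = 4.58e-08), with 57.4 ± 8.40 in BAL AM and 87.0 ± 7.06 in Host AM. A region inside Patj (chr4:98555244-98557252) changed by 4.25 ± 0.79 (0.000303). A region within 1 kb of an end of Il1a (chr2:129300031-129303112) went from 76.2 ± 19.5 to 4.92 ± 4.99 (-3.74 ± 0.75, 0.000857), with 6.36 ± 1.95 in BAL AM and 5.48 ± 1.71 in Host AM. Another, between genes near Apol8 (chr15:77739763-77743145), changed by -3.73 ± 0.71 (0.000464). Of the 20 regions named by the rule 18 kept their call without any 1 library, and of 46 named loci 18 did.

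As a set, antigen presentation rose in texAM, with 6 of 21 loci higher, none lower and 15 not passing (7 and 0 adjusted over the list alone, 8 and 0 at an unadjusted p under 0.05). Its camera adjusted p was 0.00346, with an adjusted p = 0.209 with an estimated correlation. Cytoskeleton and adhesion loci fell, 10 of 33 against 2 that rose (14 and 3 adjusted over the list alone), with Myh9, a non-muscle myosin, at -0.87 ± 0.11 (8.14e-07). The camera adjusted p for that list was 0.0463, an adjusted p = 0.209 with an estimated correlation, and it did not pass without texAM 3 (0.156) or without Host AM 3 (0.0572), which enters through the shared fit. Alveolar macrophage identity had 4 loci that rose and 8 that fell of 32 (5 and 12 adjusted over the list alone, camera adjusted p = 0.151). Monocyte and other tissue macrophage had 1 and 6 of 24 (0.595), inflammatory NF-kB 3 and 5 of 29 (0.723), TGF-beta response 3 and 4 of 20 (0.919) and oxidative stress and hypoxia 2 and 3 of 24 (0.723). Lipid and cholesterol handling had 2 that rose, among them the cholesterol exporter Abca1 (0.78, 7.81e-05), which did not pass with total intervals (0.26) or 10-kb bins (0.13), and 2 that fell of 32 (0.723). Cell cycle and self-renewal had 2 and 1 of 29 (0.776), with a median of -0.11 and a test pointing up. Interferon response had 0 that rose and 1 that fell of 23 (0.242), or 4 higher and 2 lower at an unadjusted p under 0.05 and none when adjusted over the list alone, with a median of 0.20 and a test pointing up. Of the markers of other cell types 2 rose and 5 fell, among them Col3a1 (-2.75), and of 55 3 were higher and 16 lower at an unadjusted p under 0.05, with a median of -0.43 (sorted against unsorted cells). Over all loci 5.03% rose and 6.57% fell. With regions within 1 kb of a gene end alone, Smurf1 (-0.45), Pparg (-0.41) and Myh9 (-0.15) did not pass, nor did the antigen presentation list (adjusted p = 0.0799).

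Of the loci given in every comparison, Siglecf was at 0.67 (adjusted p = 0.0133), but at -0.01 with 10-kb bins, and did not pass without texAM 1 (0.0646) or texAM 3 (0.052). Car4 was at -1.05 (0.0149), which did not pass without exAM 2 (0.0725), texAM 1 (0.0913) or texAM 3 (0.0543). Maf (0.62, 0.133) and Ptprc (0.17, 0.47) did not pass. Scaled by total intervals the regions split into 500 higher and 7846 lower (median region -0.59), and by 10-kb bins into 313 higher and 9514 lower (median region -0.74). The share of called regions that were higher in texAM went from 53.4% to 47.1% without exAM 1, 42.6% without exAM 2 and 46.3% without exAM 3, to 41.3% with thinning, 43.7% of 5510 with limma-trend and 43.4% with background subtracted, and to 75.8% without texAM 1. The count of 3012 was 1757 without exAM 2, 1130 without texAM 1, 1729 without texAM 2 and 1352 without texAM 3, and that of 1578 loci was 689 without texAM 1 and 877 without texAM 3.

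Transplanted cells were then compared with the resident cells of the same lungs, both sorted. texAM and Host AM differed in 45 of 46271 regions, 28 higher and 17 lower in texAM, while 3283 regions had an unadjusted p under 0.05. Pmepa1 was lower in texAM (-1.47 ± 0.24, adjusted p = 0.00049), at 74.8 ± 21.7 normalised counts against 230 ± 56.4 in Host AM, 82.5 ± 26.6 in exAM and 285 ± 21.8 in BAL AM. Ly6c2 was higher (1.16 ± 0.18, 9.33e-05), at 301 ± 61.3 against 137 ± 28.9 in Host AM, 94.9 ± 9.25 in exAM and 59.2 ± 18.4 in BAL AM. Most of that locus count came from 1 region between genes, at 292 ± 60.7 in texAM and 127 ± 29.1 in Host AM. A region inside Adgrl3, an adhesion receptor gene (chr5:81020705-81023362), held 22.6 ± 4.69 in texAM and 97.6 ± 9.16 in Host AM (-2.13 ± 0.36, 0.000808), with 15.7 ± 9.53 in exAM and 102 ± 7.11 in BAL AM. A region inside Mid1 (chrX:169986548-169987560), a gene at the boundary of the pseudoautosomal segment of X, had 0 counts in all Host AM libraries. Against a floor of 3 counts over the Host AM group, it was at least 32.6-fold higher in texAM and at least 23.2-fold higher in BAL AM. The region held 26.5 ± 6.238 in texAM, 32.28 ± 0.7829 in exAM and 21.02 ± 4.575 in BAL AM, so Host AM alone lacked counts there.

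Other regions named by the rule depended on single libraries. Irx2, a homeobox gene, had a region inside it (chr13:72627219-72628830) at 60.9 ± 10.2 in texAM and 10.2 ± 5.64 in Host AM (2.65 ± 0.44, adjusted p = 0.000504), with 44.99 ± 8.64 in exAM and 8.59 ± 5.22 in BAL AM, which did not pass without Host AM 2 (0.103). A region inside Gpc6, a glypican gene (chr14:117777954-117779800), held 8.33 ± 8.77 in texAM and 135 ± 29.0 in Host AM (-3.96 ± 0.69, 0.00102), with 13.6 in exAM and 103 ± 17.7 in BAL AM, and did not pass without texAM 1 (0.145). Near Sema3e (chr5:14024923-14026470) the change was 1.74 ± 0.30 (0.000808), or an adjusted p of 0.0825 without Host AM 2, and it did not pass with 10-kb bins (1.34). Of the 20 regions named by the rule, those at Adgrl3 and Mid1 kept their call without any 1 library, although Adgrl3 did not pass with counts around region centres (adjusted p = 0.155), nor Mid1 without texAM 2 and Host AM 2 together (0.101). The count of 45 regions was 18 without Host AM 2, and the split then turned to 5 higher and 13 lower. It was 2 and 9 without texAM 2 and Host AM 2 together, and 37 and 92 with limma-trend. A fit with a replicate block gave 76 regions. Scaling changed the split to 15 higher and 79 lower with total intervals (median region -0.34) and to 8 higher and 73 lower with 10-kb bins (median region -0.40).

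Among loci, 22 were higher and 29 lower in texAM than in Host AM. The count of 51 was 13 without texAM 1, 29 without texAM 3 and 24 without Host AM 2. Of the 32 alveolar macrophage identity loci 1 rose, Marco (0.57 ± 0.13, adjusted p = 0.0351), which did not pass without texAM 1 (0.687), texAM 3 (0.125), Host AM 2 (0.351) or Host AM 3 (0.12), nor when scaled by total intervals (0.25) or 10-kb bins (0.18). As a set the list was higher in texAM (camera adjusted p = 0.00695, adjusted p = 0.446 with an estimated correlation), with a median of 0.07, and this call did not hold without texAM 1 (0.0758) or Host AM 2 (0.332). Antigen presentation had no member past the threshold (0 higher and 4 lower at an unadjusted p under 0.05, camera adjusted p = 0.0555), H2-Eb1 being at -1.17 (0.3) and H2-Ab1 at -0.69 (0.345). Pmepa1 was the member of the TGF-beta response list that fell and Ly6c2 the member of the monocyte list that rose. No locus passed in the other 14 lists by limma-voom, and of 55 markers of other cell types 1 was higher and 5 lower at an unadjusted p under 0.05. Pmepa1 did not pass with counts around region centres or with regions within 1 kb of a gene end alone (-0.37), nor Ly6c2 with 10-kb bins (0.78, 0.131), with regions within 20 kb (0.00) or without the short-fragment libraries texAM 2 and Host AM 2 (0.86, 0.108). Pparg (0.21, 0.751), Car4 (0.37, 0.858), Siglecf (0.25, 0.789), Maf (-0.13, 0.941) and Ptprc (0.00, 0.999) did not pass.

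Where texAM and Host AM differed, texAM mostly lay on the side of the cultured cells. Of the 28 regions higher in texAM, 22 had also been called higher in exAM than in BAL AM, against 3.44 expected for independent lists (Fisher's exact p = 1.64e-15), and of the 17 lower in texAM 11 had been called lower in exAM, against 1.24 expected (2.59e-09). These comparisons share no library but come from 1 fit. Fisher's test also counts regions as independent, although some are neighbours, as at Irx2, so its p-values are too small. Without Host AM 2 the counts were 3 of 5 higher (0.615 expected) and 10 of 13 lower (0.951 expected), without texAM 1 22 of 27 and 3 of 4, and without texAM 2 and Host AM 2 together 1 of 2 and 7 of 9. With limma-trend they were 32 of 37 higher (4.55 expected) and 48 of 92 lower (6.73 expected), and 6 of those lower had been higher in exAM. Across all 46271 regions the changes correlated with r = 0.217 and rho = 0.175, where regions are not independent replicates. The culture score, built from 5440 higher and 2813 lower regions, was -1.96 ± 0.04 in BAL AM, 0.99 ± 0.15 in exAM, -1.28 ± 0.09 in texAM and -1.64 ± 0.03 in Host AM (SD, n = 3). texAM lay 0.36 above Host AM, 12.3% of the distance from BAL AM to exAM, or 14.6% on average (13.1 to 16.9%) with that distance taken in libraries left out of the choice of regions and 18.2% after subtracting uncalled regions with the same BAL AM count per kb, with each texAM library above each Host AM library and an exact two-sided permutation p of 0.1, the smallest that 3 against 3 allows. Host AM also lay 0.32 above BAL AM (exact permutation p = 0.1), which turned to -0.05 (p = 0.5) after subtracting such regions. The regions of the score were chosen with the BAL AM libraries, which alone can place another group above BAL AM. These p-values are therefore no independent test. With the 1000 strongest regions of each direction, the score difference between texAM and Host AM was 0.71, or 14.2% of a distance of 4.97 between BAL AM and exAM.

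**Figure D3:**
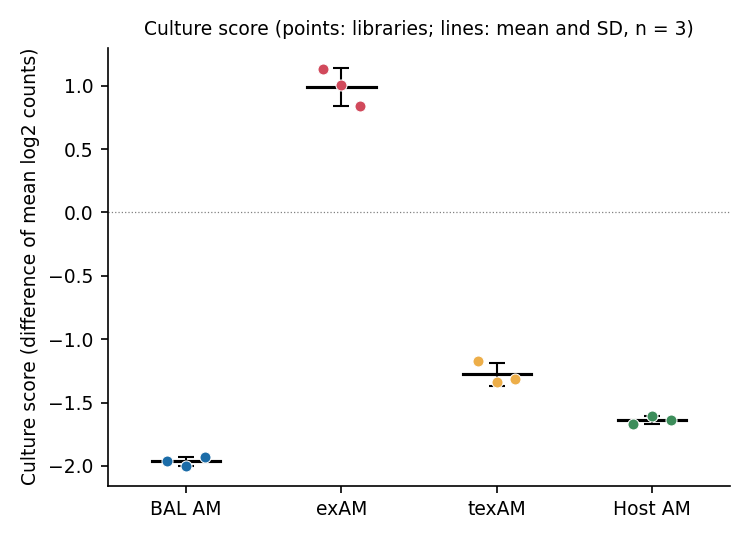
Points are the culture score of each library, the mean log2(normalised count + 1) over regions higher in exAM than in BAL AM minus the mean over regions lower, with the group mean and SD. texAM libraries (-1.28 on average) lie between Host AM (-1.64) and exAM (0.99), close to Host AM.

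Transplanted cells were also set against the lavage cells, from which they differed in culture, transplantation, sort and source. texAM differed from BAL AM in 561 regions, 404 higher and 157 lower, and in 322 loci, 205 higher and 117 lower. A region between genes near Irx2 (chr13:72598778-72601133) held 66.2 ± 13.5 in texAM and 5.16 ± 0.789 in BAL AM (3.61 ± 0.45, adjusted p = 6.47e-08), with 59.2 in exAM and 16.8 in Host AM. A region between genes near Mrps28 (chr3:8766171-8768497) held 3.25 ± 2.82 in texAM and 64.0 ± 2.18 in BAL AM (-3.95 ± 0.79, 0.00167), with 4.66 in exAM and 31.2 in Host AM. Of the regions lower in texAM 53.5% lay within 1 kb of a gene end, against 28.03% of all tested. The split was 125 higher and 31124 lower with total intervals (median region -1.23) and 62 and 39462 with 10-kb bins (median region -1.70), and the count of 561 was 256 without BAL AM 1 and 246 without texAM 1, and 915 in a fit with a replicate block. Of the called regions 72.0% were higher, against 35.3% of 136 with thinning and 45.7% of 460 with limma-trend.

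Host AM were compared with BAL AM to measure the difference between sorted resident cells and lavage cells with no culture between them. Vim, which encodes the intermediate filament vimentin, was lower in Host AM (-1.21 ± 0.11, adjusted p = 6.47e-10), at 310 ± 52.0 normalised counts against 702 ± 80.1. Actb, cytoplasmic actin, was at -0.96 ± 0.11 (7.96e-08), Egr2, a transcription factor, at -0.85 ± 0.14 (0.000178), and Csf2rb, the beta chain of the GM-CSF receptor, at -0.74 ± 0.12 (7.51e-05). A region between genes near Chil3 (chr3:106141210-106145964) held 70 ± 21.6 in Host AM and 224 ± 28.02 in BAL AM (-1.90 ± 0.19, 2.29e-11), with 16.9 ± 7.25 in exAM. A region inside Olr1, a receptor for oxidised lipoprotein (chr6:129485879-129492185), held 33.5 ± 10.9 against 112 ± 16.6 (-1.77, 7.1e-07). Higher in Host AM was a region inside Esrrg, an orphan nuclear receptor gene (chr1:187895129-187896827), at 28.8 ± 9.45 against 4.77 ± 1.13 (2.31, 0.0013), with 36.8 ± 6.48 in texAM.

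In all, 226 regions were higher and 181 lower in Host AM (407 of 46271), as were 108 and 94 loci. Of the lower regions 58.6% lay within 1 kb of a gene end. Alveolar macrophage identity fell as a set, with 11 of 32 loci lower, none higher and 21 not passing (15 lower adjusted over the list alone, 16 lower and 0 higher at an unadjusted p under 0.05), a mean of -0.35 log2 and a camera adjusted p of 4.35e-21 (adjusted p = 0.00189 with an estimated correlation). Cytoskeleton and adhesion also fell, with 6 of 33 lower and none higher (9 adjusted over the list alone, camera adjusted p = 3.5e-11, adjusted p = 8e-04 with an estimated correlation). Inflammatory NF-kB had 2 of 29 lower (4 adjusted over the list alone), Nlrp3, the inflammasome sensor, at -0.57 (0.00061) and Tnfaip2 at -0.45 (0.00495), with a camera adjusted p of 0.00333 and an adjusted p = 0.0787 with an estimated correlation. TGF-beta response had 1 of 20 lower, Tgfbi (5 adjusted over the list alone), at 0.0113 and an adjusted p = 0.0655 with an estimated correlation. Tgfbi itself (-0.47) did not pass without BAL AM 1 (0.107) or Host AM 2 (0.15). The percent of intervals in regions and the share of short fragments moved with these lists, as given above for the sorted groups.

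Antigen presentation was higher in Host AM as a set, with 3 of 21 loci that rose and none that fell (5 adjusted over the list alone), at a camera adjusted p of 0.0292 and an adjusted p = 0.239 with an estimated correlation, but H2-Ab1 (0.90) turned to -0.03 and -0.48 and Cd74 (0.51) to -0.38 and -0.80 with total intervals and 10-kb bins. Neither H2-Ab1 (0.133 and 0.164) nor Cd74 (0.337 and 0.056) passed without BAL AM 1 or Host AM 2, and Cd74 did not without BAL AM 3 (0.0695) or Host AM 3 (0.205). The set did not pass without BAL AM 2 (0.127), BAL AM 3 (0.0803), Host AM 2 (0.101) or Host AM 3 (0.0572). Oxidative stress and hypoxia passed as a set (0.0432, adjusted p = 0.0954 with an estimated correlation) with no single locus past the threshold (2 rose adjusted over the list alone, 6 were higher and 0 lower at an unadjusted p under 0.05). It did not pass without BAL AM 1 (0.131), BAL AM 3 (0.0506), Host AM 2 (0.156) or Host AM 3 (0.115), nor with the replicate block (0.0642), and pointed down with 10-kb bins (0.302). Lipid and cholesterol handling had 3 of 32 lower, among them Plin2, a lipid droplet protein (-0.62, 4.97e-05), and none higher (3 rose and 5 fell adjusted over the list alone, camera adjusted p = 0.112), with a median of 0.00 and a mean of -0.02. In the monocyte list Ly6c2 rose (1.19, 8.9e-05), a direction that turned with 10-kb bins (-0.12). Its locus count came mostly from 1 region between genes (chr15:75085428-75087111), at 127 ± 29.1 in Host AM and 56.3 ± 19.1 in BAL AM. No locus passed in the interferon, cell cycle or other cell type lists by limma-voom, over all loci, and at an unadjusted p under 0.05 these had 3 higher and 0 lower, 2 and 1, and 1 and 2.

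Of the loci given in every comparison, Pparg (-0.25, adjusted p = 0.274), Car4 (-0.75, 0.146), Siglecf (-0.16, 0.713), Marco (-0.11, 0.75), Maf (0.14, 0.828) and Ptprc (-0.07, 0.861) did not pass between Host AM and BAL AM. Scaled by total intervals Pparg (-1.13), Siglecf (-1.06), Marco (-1.01), Car4 (-1.65) and Ptprc (-0.95) passed as lower, as the median region then lay at -0.88 and the split was 69 higher and 26095 lower. With 10-kb bins the split was 30 higher and 36842 lower, with the median region at -1.29. Counted around region centres, Actb (-0.39), Egr2 (-0.33) and Csf2rb (-0.49) did not pass, nor did the regions near Chil3 and inside Olr1 (-1.46) and Esrrg (2.01). Of the 407 regions 55.5% were higher, against 32.0% without BAL AM 1, 44.9% without BAL AM 2, 25.7% with thinning and 41.8% with limma-trend, so the split turned. The counts of 407 regions and 202 loci were 178 and 92 without BAL AM 1, and the locus count was 122 without Host AM 2.

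**Figure D4:**
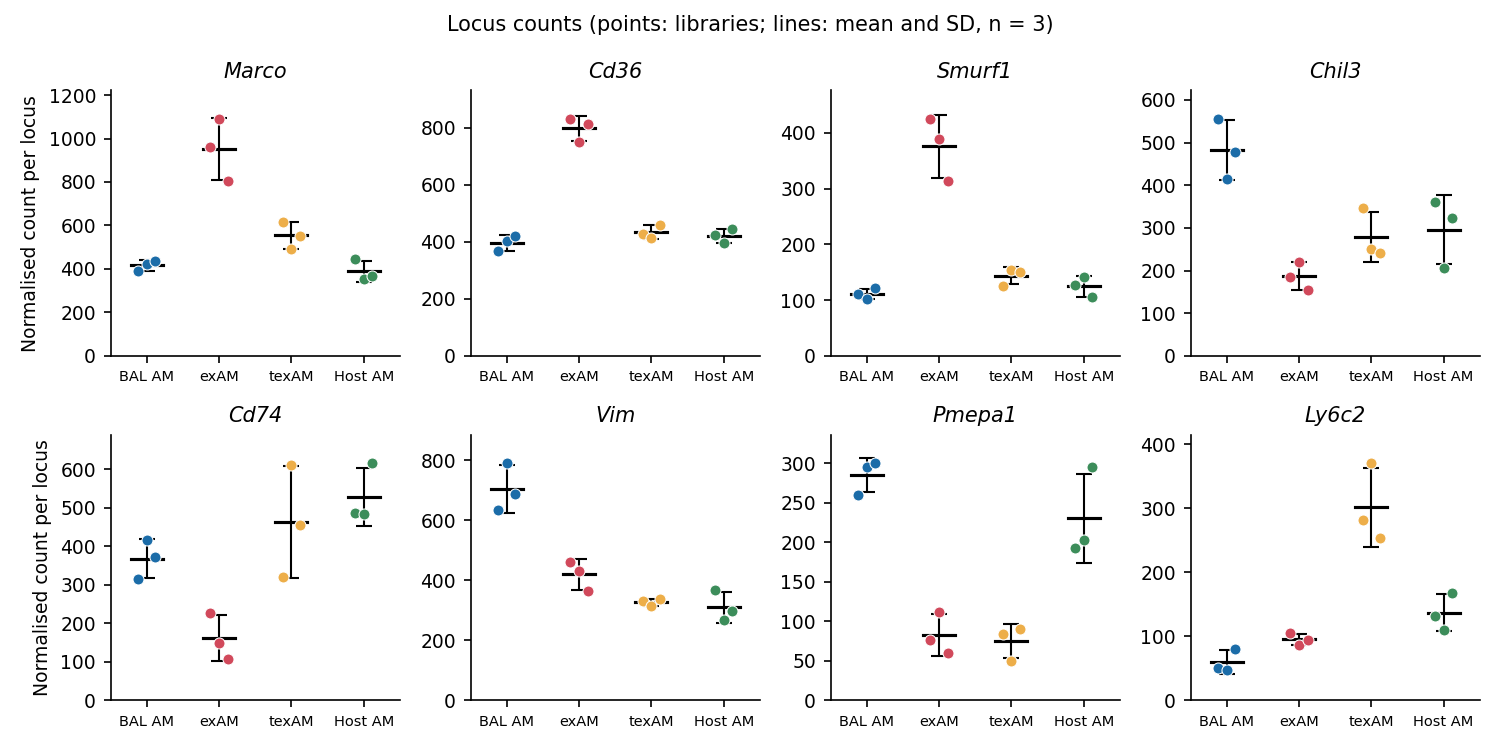
Points are normalised counts per library, summed over the regions of each named locus, for 8 loci in the 4 groups, with the group mean and SD, under the scaling by consensus regions. Marco, Cd36 and Smurf1 are highest in exAM, although the rises at Marco and Cd36 over BAL AM do not pass when scaled by 10-kb bins, Cd74 is lowest in exAM, and Pmepa1 is low in both exAM and texAM.

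The culture effect (exAM against BAL AM) was compared directly with the difference between transplanted and resident cells (texAM against Host AM), each of them setting libraries with the same sort side by side. It passed in 915 regions, 432 with a higher and 483 with a lower culture effect, and 866 of these had been called between exAM and BAL AM. Inside Atp2c2, a calcium pump gene (chr8:119750698-119755067), the culture effect was 5.11 and texAM against Host AM -0.23, a difference of 5.34 ± 0.95 (adjusted p = 0.000557). Between genes near Mtmr7 (chr8:40647001-40648922) effects of -3.55 and 0.10 differed by -3.65 ± 0.69 (0.0012). The split was 241 higher and 1481 lower with total intervals (median region -0.31) and 152 and 2462 with 10-kb bins (median region -0.58). The share with a higher culture effect (47.2%) turned to 55.9% without exAM 1, 59.7% without exAM 2, 52.8% without exAM 3 and 54.0% without Host AM 2. With all libraries kept it turned to 57.19% with limma-trend, 52.25% with the replicate block and 52.26% in 500 bp. It was 51.66% with sample weights, 51.48% with no filter and 50.3% with cut ends. In the other settings with all libraries, lower effects stayed the majority. The count was 326 without texAM 1, 511 without texAM 2 and 460 without texAM 3, and 1487 in a fit with a replicate block.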

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

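The tests of other splits of the libraries for regions and loci, of short fragments, of depth, of background for the culture score of Host AM against BAL AM, of strain variants, of other cell types and of regions outside the direction of culture were chosen only after the results were seen.

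The effect of culture differed from the difference between texAM and Host AM in 915 regions, which a test of the difference itself singled out. Of 100 splits of the libraries into groups of the same sizes, 10 gave as many regions, the real one included, so chance was not excluded for this count. The highest other split gave 3385. The 9 other splits as large kept exAM and BAL AM apart and mixed texAM with Host AM, which points to a structure of the samples, the separation of exAM from BAL AM. They keep the culture contrast and so do not test it. The highest count among the 90 splits that mixed exAM with BAL AM was 0. Mixing groups that differ raises the spread and fixes that outcome, so the splits cannot decide on chance. Among regions named by the rule, the difference on the log2 scale was 5.34 at Atp2c2, 5.15 at Dennd11, 4.83 at Stac, 4.45 at Dlg2, 4.05 at Pard3, 4.05 at Serpina3a, 3.96 at Apol8, 3.91 at Cd38, 3.59 at Ints9 and 3.57 at Galnt18. It was -5.51 at Gpa33, -4.14 near Chil3, -4.00 at Patj, -3.86 at Pdhx, -3.67 at Cpne5, -3.65 at Mtmr7, -3.65 at Ccdc126 and -3.60 at Poc1b. The fitted differences of -6.04 at Fgd4 and -5.21 at Mid1 depend on the prior count, since exAM had 0 counts at Fgd4 and Host AM 0 at Mid1, and are no bounds. Against a floor of 3 counts over the group, the Fgd4 region (chr16:16472513-16473860) was at least 30.5-fold higher in BAL AM than in exAM. At Mid1 texAM against Host AM passed (5.91 fitted, adjusted p = 0.000271) and lay further from 0 than the culture effect (0.70). At Galnt18 (-3.58 against -0.01) and Cd38 (-2.40 against 1.51) texAM against Host AM did not pass (adjusted p = 0.0545 and 0.529), and the difference at Galnt18 was 1.84 without texAM 1 (0.237). Without some single library the calls at Apol8, Ccdc126, Cd38, Cpne5, Dlg2, Galnt18, Ints9, Pdhx and Serpina3a were lost.

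Intervals on chromosome Y, which no comparison used, were present in all 12 libraries at 38.2 to 100.2 ppm of a library's intervals, with a median of 80.13 ppm.

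texAM lay on the exAM side of Host AM over regions that differed between exAM and BAL AM, by 0.362 on the culture score. Against regions with the same BAL AM count per kb that had not been called, which removes a shared rise in background, the distance was 0.451, and it was 0.365 without short fragments and 0.457 with every library thinned to the same total, over fewer regions. As shares of the distance from BAL AM to exAM these were 18.2%, 12.1% and 14.1%, against 12.3%, so none of these technical differences accounts for the whole distance. The rise from 0.362 to 0.451 came from texAM 2, the shallowest library. Its matched regions moved by 0.097, against 0.403 in texAM 1, 0.367 in texAM 3 and 0.352 to 0.396 in Host AM. Strain variants in Host AM would leave BAL AM, which comes from the other strain, nearer to texAM. BAL AM lay nearer to Host AM in 88.89% of the 45 regions called between texAM and Host AM, which were chosen without BAL AM (exact Clopper-Pearson 95% interval 75.95 to 96.29). Among all tested regions the share was 60.44%. The excess goes against such variants in most of the 45, but texAM libraries correlated less with each other (0.765) than Host AM libraries (0.835). Choosing regions on the noisier group can also raise the share. Of the 45, 34 are 0.412% of the 8253 regions of the score. Over the score regions, after subtracting matched regions, texAM lay 0.397 from BAL AM and Host AM -0.054. Those regions were chosen with the BAL AM libraries, which can shift BAL AM from both groups, so variants stay open for the distance. The distance of Host AM from BAL AM in the same direction (0.324) went to -0.054 (exact permutation p = 0.5) with matched regions, as more background in Host AM predicts. A retained trace of culture in texAM, transplantation itself and the different origin of the cells stay open beside variants, as untested.

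Alveolar macrophage identity loci were lower in Host AM than in BAL AM, with a mean of -0.35 log2. Higher background in Host AM does not account for this, since 0% of 10000 random lists matched on the BAL AM count per kb had a mean as low (95% of their means lay between -0.08 and 0.12). Other cell types in Host AM would raise their markers, and 0 of 55 marker loci rose (limma-voom, median -0.02, 1 higher and 2 lower at an unadjusted p under 0.05). Only markers with enough counts in the deposited regions were measured, 7 of 15 for T cells and 4 of 13 for fibroblasts. The median count of the 55 loci was 38.45, against 54.75 over all loci, and recovery at lower counts was not tested. These markers therefore cannot exclude other cell types. Monocytes and other macrophages are not among these types. Host AM were sorted for SiglecF and CD11c, whereas BAL AM were unsorted. In their list 1 of 24 loci rose, Ly6c2 (1.19, but -0.12 with 10-kb bins), mostly through 1 region between genes. The list did not pass (camera adjusted p = 0.772). They stay open. Without short fragments the mean of the identity list was -0.362. Sort, tissue source, strain and history in the recipient differed together between these groups, and each could contribute, untested.

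Outside the direction of culture, 12 regions were called between texAM and Host AM. BAL AM lay nearer to Host AM in 58.33% of them (exact Clopper-Pearson 95% interval 27.67 to 84.83), against 60.44% of all tested regions. The 12 are what is left after removing regions chosen partly on BAL AM. Strain variants in Host AM could therefore neither be separated from other sources nor excluded. Of the 12, 2 lay within 20 Mb of Ptprc, the locus that carries the CD45.1 allele, at Kif21b and Mapkapk2, which is 10.12 times the share of all regions (Fisher's exact p = 0.016). Of all 45 called regions the same 2 are 4.44%, against 1.65% of all tested, and of the 407 regions called between Host AM and BAL AM 15 (3.69%) lay there. This possibly reflects sequence carried with that allele, but rests on 2 regions, and Mapkapk2 lost its call without each of the 6 libraries in turn (adjusted p 0.0539 to 0.724). Kif21b (chr1:136139351-136142751, inside the gene) held 43.1 ± 5.73 in Host AM and was higher in texAM by 1.44 (adjusted p = 0.000398), at 122.6 ± 12.96. BAL AM (100.3 ± 7.694) and exAM (106.9 ± 18.3) lay nearer to texAM there. Host AM was also lower than BAL AM in this region (-1.168, limma-voom adjusted p = 0.000179). A short region between genes near Col19a1 (chr1:24612617-24612818), named after its values were seen, held 60.5 ± 1.76 in Host AM against 0.138 in BAL AM, 0.363 in exAM and 0.832 in texAM. It may lie in a nuclear copy of mitochondrial DNA, which was not tested here without a genome sequence.

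With 3 libraries against 3 there are 10 splits, so no share of splits can go under 0.1 for the comparisons of pairs of groups. Each other split mixes the groups, which raises the spread wherever they differ and lowers the calls. Low counts in the other splits are therefore no support for the real one. The real split gave 9078 regions for exAM against BAL AM (highest other 0), 3012 for texAM against exAM (5), 45 for texAM against Host AM (0), 561 for texAM against BAL AM (5) and 407 for Host AM against BAL AM (4). For loci it gave 3023 (0), 1578 (0), 51 (0), 322 (2) and 202 (0) in the same order. For lists of genes the real split gave 1 for exAM against BAL AM (highest other 2), 2 for texAM against exAM (0), 1 for texAM against Host AM (2) and 6 for Host AM against BAL AM (3). Splits with a result as large, the real one included, numbered 4, 1, 3 and 1 of 10 for these lists and 1 of 10 for each count of regions and loci.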

How the results depend on the processing

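Counting cut ends, leaving out short fragments or the libraries texAM 2 and Host AM 2, cyclic loess, background subtraction, gene ends in place of promoters, and thinning of the culture score were chosen only after the data were seen. Counts of calls stayed within 1.5 times their main value under total counts in regions, quantile scaling, no filter, overlap of 1 bp, duplicates counted once, sample weights, the 6 libraries alone and autosomes alone. For the values below the cause was not tested, except that thinning, the stricter thresholds and left-out libraries test fewer counts, smaller sets or fewer samples by construction. Motifs were not run without a genome.

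Regions called are given in the order exAM against BAL AM, texAM against exAM, texAM against Host AM, texAM against BAL AM, Host AM against BAL AM and the difference of effects. Total intervals gave 20472, 8346, 94, 31249, 26164 and 1722, and 10-kb bins gave 27035, 9827, 81, 39524, 36872 and 2614, because the median region then moved. Counts in 500 bp gave 4482, 1368, 27, 271, 169 and 266, thinning 691, 860, 8, 136, 70 and 71, a 1.5-fold test 2350, 216, 5, 98, 35 and 79, and a rate of 0.01 gave 5152, 968, 24, 278, 211 and 214. Limma-trend gave 4568, 5510 and 129 in the first 3 and 79 for Host AM against BAL AM. At least 30 counts gave 4990 in the first and 536 in the last. Without short fragments texAM against Host AM gave 23 and the difference 437, and without texAM 2 and Host AM 2 they gave 11 and 382. Leaving out 1 library gave 6481 to 7516, 1130 to 2302, 18 to 40, 246 to 487, 178 to 372 and 326 to 968, with the lowest values without exAM 2, texAM 1, Host AM 2, texAM 1, BAL AM 1 and texAM 1.

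Loci called, for exAM against BAL AM, texAM against exAM, texAM against Host AM and Host AM against BAL AM, were 7482, 5135, 162 and 10590 with total intervals, 9716, 5646, 83 and 12339 with 10-kb bins, 425, 74, 6 and 12 with a 1.5-fold test, 1841, 692, 23 and 104 at 0.01, and 1145, 526, 12 and 122 within 1 kb of a gene end. Thinning gave 1079, 25 and 72 without texAM against exAM, 500 bp gave 928, 28 and 115 without exAM against BAL AM, and limma-trend gave 1836 in the first and 67 in the last. For texAM against Host AM, leaving out short fragments gave 32 and leaving out texAM 2 and Host AM 2 gave 17, and the latter gave 113 for Host AM against BAL AM. Leaving out 1 library gave 2300 to 2667, 689 to 1381, 13 to 38 and 92 to 189.

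Lists called in the same order were 0, 0, 0 and 2 with an estimated correlation. For exAM against BAL AM fry gave 7 and the bins 4. For texAM against exAM fry gave 9, and distances of 20 and 100 kb 1 each. For texAM against Host AM these distances gave 3 each, leaving out short fragments 2, and the bins and cyclic loess 0. Leaving out 1 library gave 1 to 1, 1 to 4, 0 to 2 and 4 to 6. The culture score distance of 0.362 was 0.706 with 1000 regions per direction, 0.457 when thinned, and 0.311 to 0.41 without 1 library.

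Directions turned at these loci. For exAM against BAL AM with 10-kb bins they were Nr1h3 (-0.131), Tpm1 (-0.036), Emp1 (-0.091), Ptk2 (-0.102), Ccnb1 (-0.009), Gpnmb (-0.04), Pgk1 (-0.054), Ldha (-0.243), Prdx1 (-0.329), Rnase2a (-0.357), Ear6 (-0.571), Tcf4 (-0.488), Vwf (-0.426), Pparg (-0.433) and Car4 (-0.304), and with total intervals Prdx1 (-0.007), Rnase2a (-0.025), Ear6 (-0.239), Tcf4 (-0.155), Vwf (-0.095) and Pparg (-0.107). Ptgs2 turned within 20 kb (-0.46) and within 1 kb of a gene end (-0.459), where Ear6 also turned (-0.284). For texAM against exAM they were Abcg1 with total intervals (-0.201) and bins (-0.322), Ptgs2 within 100 kb (0.107), Cdkn1a with bins (-0.061) and gene ends (-0.126), and Ndrg1 (-0.034) and Siglecf (-0.009) with bins. For Host AM against BAL AM they were H2-Ab1 (-0.033) and Cd74 (-0.377) with total intervals, and H2-Ab1 (-0.482), Cd74 (-0.795) and Ly6c2 (-0.121) with bins.

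With the replicate number as a replicate block, texAM against exAM gave 4283 regions and texAM against Host AM 76. It gave 915 for texAM against BAL AM and 1487 for the difference of effects. The oxidative stress list of Host AM against BAL AM lost its call (camera adjusted p = 0.0642), and the culture score distance was 0.362. Deviations of libraries with the same number correlated between -0.0696 and 0.0332, over 3 pairs in each comparison. These values show no pairing by number but do not exclude it. texAM 2 and Host AM 2, which carry the same number, had the most short fragments (62.2% and 58.6%). Of the named loci 195 kept their side of the threshold with the block, 3 lost it and 1 gained it, and of the named regions 117 kept it and 3 lost it.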

Other observations

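The counts of regions per locus, their shuffling and the loci named for them were chosen only after the values were seen. Between exAM and BAL AM, called regions of the same direction gathered at single loci more than when calls were shuffled 1000 times between regions of similar mean count. At 69 loci at least 5 regions were higher in exAM and none lower (9.62 on average and 24 at most when shuffled), at 45 loci at least 5 were lower and none higher (0.493 and 3), and at 10 loci at least 3 went each way (25.1 and 13 at the fewest). At Cd36 13 of 20 regions were higher in exAM, at Marco 12 of 21 and at Smurf1 12 of 15. Itpr2, an intracellular calcium channel gene, had 17 of 35 higher and 1 lower, and Snd1 had 13 of 23. Prickle2, a planar cell polarity gene, had 10 of 15 higher, and its locus rose by 1.64 (adjusted p = 1.97e-13) and was also higher in texAM than in Host AM (0.66, 0.016). Plpp3, a lipid phosphatase gene, had 12 of 18 higher (1.01, 3.44e-11). Lower in exAM were 15 of 42 regions at Runx1, a transcription factor of blood cells (-0.61, 9.69e-08), 13 of 20 at Rftn1, a lipid raft protein gene (-1.29, 7.56e-08), 8 of 10 at Rarb, a retinoic acid receptor gene (-1.85, 1.48e-09), and 9 of 12 at Rnf217 (-1.95). At Foxn3 9 of 27 regions were lower in exAM and 1 higher. The counts of loci depend on scaling, with 5 loci higher and 1042 lower by the same rule under 10-kb bins and 6 and 648 under total intervals.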
